A study of Homo sapiens with 14 samples.

How the data were processed

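Total RNA was sequenced after ribosomal RNA depletion with RiboZero-Gold, from stranded TruSeq libraries, in 2 preparations of primary human platelets and in 12 libraries of platelet-like particles (PLPs). PLPs are anucleate, platelet-sized fragments shed in culture by Meg01, a human megakaryoblastic leukaemia cell line. The Meg01 cells expressed either green fluorescent protein (GFP, the control) or Pelota (PELO), a factor that takes apart ribosomes stalled on an mRNA. PLPs of each kind were sampled at 0 h in 2 replicates and at 1, 2, 4 and 6 h in 1 library each. The labels do not say what started the clock at 0 h, nor whether the replicates or the times were separate cultures. The p-values therefore measure only the spread between these samples. The labels give a firefly luciferase RNA spike of 0.05 ng per 100 ng of total RNA for the PLP libraries, but no luciferase row was among the features analysed, so no scaling to the spike was possible.

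The PLP values are RPKM (reads scaled to feature length and library total), as the deposited column names state. The platelet values are whole-number read counts per transcript, as the deposited numbers show, with no header to name the 2 columns, so both were assigned only to the platelet group. The labels name the hg19 genome, CASAVA 1.8, Bowtie2 2.2.6 and TopHat2 2.0.10 with no role or order, and do not name the counting step or the annotation. The authors' PLP table was limited to 11770 features with an RPKM of at least 0.3 in 1 library, GFP 0 h replicate 1. A gene that was absent there and present elsewhere was therefore not analysed here. The limit also selects on a library used in the tests, so low features may read higher in it than elsewhere. It held 0 features at 0 RPKM, against 79 in GFP 6 h, a library of similar total. Results without that library are given below. The platelet table lists several transcripts per symbol, and how reads that overlap more than 1 of them were counted is not stated, so column sums were not used as depths.

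Of the PLP features, 33 identical copies and 34 sex-linked features were left out, which left 11703. Within each feature the RPKM values were whole multiples of 1 step once each library had its own factor (relative tolerance 1e-06), so whole reads and library totals were recovered for all 11703 features. The totals ran from 13.4 to 114.1 M reads per library. The comparisons, their tests, the gene lists and the rule for named genes were set before the data were examined. The first choice was the edgeR quasi-likelihood test on counts, with limma-trend for tables without counts. Because the deposited values were RPKM, that second test was used: limma-trend (limma 3.58.1, R 4.3.3) on log2(RPKM + 0.5), with Benjamini-Hochberg (BH) adjusted p under 0.05 as the threshold. The edgeR test on the recovered reads was added as an alternative after seeing the data. RPKM values scale each library to its total reads.

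There were 5 comparisons. PELO was compared with GFP at 0 h over the 4 libraries of that time. A line in hours per condition was fitted over all 12 libraries for the change with time in GFP PLPs, the change in PELO PLPs, and the difference between both slopes. PELO was compared with GFP over all times with hour as a factor, 6 libraries against 6. Slopes are given as the fitted log2 change over 6 h. They are relative to each library's total and are not absolute decay rates. Errors beside log2 changes are standard errors (SE) from the fit, and errors beside RPKM values or counts are standard deviations (SD). Where n = 6, the libraries are 2 of 0 h and 1 of each later time. They are not 6 replicates of 1 state, and their SD also holds change with time. In tests on simulated data of the same design, a 2-fold change was recovered in 88% of features at 0 h, 91% for the GFP slope, 89% for the PELO slope, 71% for the slope difference and 100% over all times. False calls in these tests were 8 of 143, 25 of 175, 16 of 164, 19 of 110 and 6 of 204 calls, so the slope tests exceeded the nominal rate. Each simulation changed 100 features by 1.5-fold and 100 by 2-fold, none of them at very low reads. Features were drawn independently, with no length trend and no effect shared within a library. Recovery in the real data may therefore be lower.

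Of 23 gene lists, 22 had members in the PLP table, since no mitochondrially encoded mRNA was listed. Each list was tested with camera (limma, preset correlation 0.01, and again with an estimated correlation), BH adjusted over the lists within a comparison. PELO was left out of every list. The lists were written from general knowledge of gene function, not from these samples. The rule for named genes took PELO with HBS1L and ABCE1, then the 8 largest changes in each direction past the threshold with an average of at least 4 CPM (reads scaled to the library total). Where none passed it took the 3 smallest p in each direction. From each list with a call or with 3 members past the test it took up to 4 members with the smallest p. It also took the 15 highest platelet symbols. Pseudogenes, small RNAs and unnamed loci were only counted, with exceptions stated where they are named. Levels of genes of the Y chromosome, XIST and TSIX were left out.

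No test was made between platelets and PLPs, because the tables differ in unit and features. Ranks within each table were compared over the 10206 symbols in both, with the highest transcript of a symbol as its platelet level and CPM as the PLP level. Gene positions come from GENCODE release 29 on GRCh38, since no hg19 annotation was used here. Alternatives covered the scaling (DESeq2 median of ratios), low-value filters of 5 CPM and 1 RPKM, pseudocounts of 0.1 and 1, DESeq2 1.42.0, limma-voom and edgeR 4.0.16 on the recovered reads, time as a rank, a depth-class term (under or over 40 M reads), removal of each library's trend with feature length (lowess, span 0.3), and leaving out each library in turn. PCR copies cannot be told from independent molecules in these data, so precision from depth covers counting error only. Python 3.11.15 and matplotlib 3.10.9 were used for tables and plots.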

Results

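The data comprised 12 PLP libraries from Meg01 cells, 6 with GFP and 6 with PELO overexpression, and 2 libraries of primary human platelets. The series names PELO overexpression as the manipulation of the PLPs. Library totals in GFP PLPs were 15.9 and 105.1 M reads at 0 h, 72.9 M at 1 h, 114.1 M at 2 h, 21.2 M at 4 h and 16.4 M at 6 h. In PELO PLPs they were 82.1 and 81.0 M at 0 h, 103.6 M at 1 h, 57.7 M at 2 h, 13.4 M at 4 h and 21.8 M at 6 h. All 4 libraries of 4 and 6 h were therefore among the 5 shallow ones. At these depths a count of 3 reads on a feature of 1 kb corresponds to 0.225 RPKM in the shallowest library and 0.026 in the deepest. Times after 0 h had no replicates within a condition.

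The first question was how the RNA of PLPs differed between PELO and GFP overexpression averaged over all times. PELO mRNA averaged 3.35 ± 0.348 RPKM (SD, n = 6) in GFP PLPs and 84.5 ± 5.29 RPKM (SD, n = 6) in PELO PLPs, a log2 change of 4.47 ± 0.06 (SE). Its gene lies on chromosome 5 at 52787940 to 52804046 on the plus strand, within the span of ITGA1 on the same strand, and ITGA1 had no row in the PLP table. HBS1L, the GTPase that partners PELO on stalled ribosomes, rose from 8.05 ± 0.386 to 10.1 ± 0.421 RPKM (SD, n = 6 each). The HBS1L log2 change was 0.31 ± 0.04 (limma, BH adjusted p = 0.00817), and the gene lies on chromosome 6 at 134960378 to 135103056 on the minus strand. ABCE1, the ATPase that splits ribosomal subunits in the same pathway, had a log2 change of 0.02 ± 0.04 (limma, BH adjusted p = 0.822). Of the 20 measured members of the list of ribosome rescue and quality control factors other than PELO, HBS1L was the 1 that rose, and none fell (1 and 0 adjusted over the list alone).

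**Figure D1:**
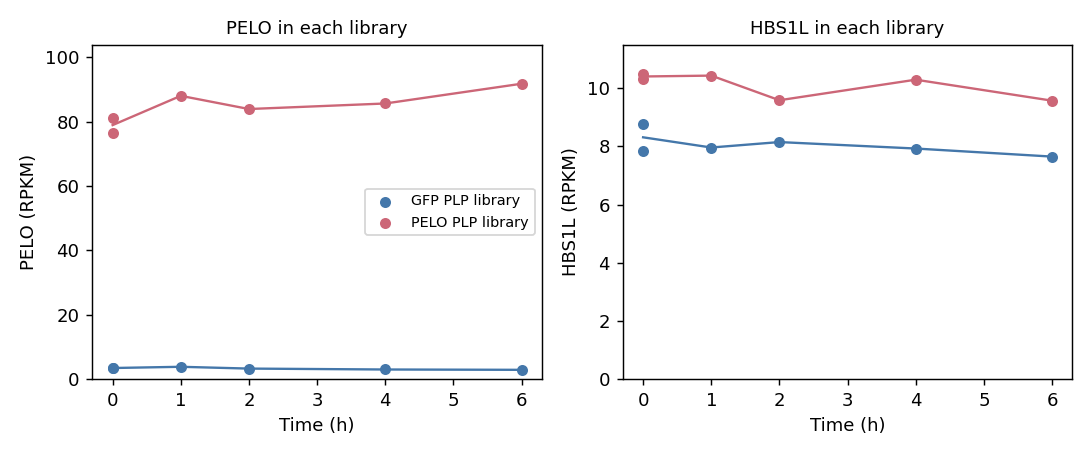
RPKM of PELO (left) and HBS1L (right) in each PLP library against time in hours, with 1 point per library and lines through the mean at each time. PELO averaged 3.35 RPKM in GFP and 84.5 in PELO PLPs, and HBS1L averaged 8.05 and 10.1.

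Interferon-stimulated mRNAs were higher in PELO PLPs as a group. Of 30 measured, 9 rose and none fell, with counts of 21 and 3 adjusted over the list alone. OASL rose by 0.32 ± 0.04 on the log2 scale, IFIT1 by 0.29 ± 0.04, MX1 by 0.23 ± 0.03, HERC5 by 0.23 ± 0.03 and ISG15, a ubiquitin-like modifier, by 0.36 ± 0.07. The 3 members that fell when adjusted over the list alone were IFITM1, IFITM2 and IFITM3, named here after their values were seen. The list median was 0.17 (camera with limma, BH adjusted p = 7.48e-12, and adjusted p = 0.0399 with an estimated correlation). Between hours the median difference between PELO and GFP libraries ran from 0.09 at 2 h to 0.19 at 4 h.

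Glycolytic mRNAs were lower in PELO PLPs. Of 23 measured, 4 fell and none rose, with 12 falling when adjusted over the list alone. The 4 were ALDOC, an aldolase (log2 change -0.26 ± 0.04), HK2, a hexokinase (-0.22 ± 0.03), ENO2, an enolase (-0.25 ± 0.05) and PFKFB4, which sets the level of fructose 2,6-bisphosphate (-0.20 ± 0.04). The list median was -0.09 (camera with limma, BH adjusted p = 2.85e-09, and adjusted p = 0.0399 with an estimated correlation). EGLN3, an oxygen-dependent prolyl hydroxylase that is not on this list, had the largest fall of all genes named by the rule. It averaged 15.8 ± 1.40 RPKM in GFP and 11.4 ± 0.657 RPKM in PELO PLPs (SD, n = 6 each), a log2 change of -0.45 ± 0.04 (limma, BH adjusted p = 0.000462).

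Cell cycle and erythroid mRNAs were higher in PELO PLPs. Of 39 cell cycle and proliferation mRNAs, 4 rose and none fell (19 and 0 adjusted over the list alone): RRM2, a ribonucleotide reductase subunit (log2 change 0.23 ± 0.04), NUSAP1 (0.18 ± 0.03), BIRC5, survivin (0.26 ± 0.05) and CCNA2, cyclin A2 (0.19 ± 0.04). Of 24 erythroid markers, CA1 (0.25 ± 0.04) and HBG1, a fetal globin (0.35 ± 0.06), rose, and 9 rose when adjusted over the list alone. HBB (0.43 ± 0.09) and HBA1 (0.25 ± 0.06) did not pass over all genes (limma, BH adjusted p = 0.0525 and 0.0575). Both lists kept their call with an estimated correlation (camera with limma, BH adjusted p = 0.0399 for each).

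Replication-dependent histone mRNAs, whose genes are expressed in S phase and most of which carry no poly(A) tail, had 8 of 53 members higher and none lower (49 and 0 adjusted over the list alone). HIST1H2AL rose by 0.46 ± 0.08, HIST1H2BO by 0.43 ± 0.07, HIST1H2BF by 0.32 ± 0.05 and HIST1H1B by 0.30 ± 0.05 on the log2 scale. The list call of 8.89e-29 (camera with limma, BH adjusted p) was lost with an estimated correlation (adjusted p = 0.225). At 1 h the list's median difference per gene between the PELO and GFP libraries was -0.12, against 0.45 at 0 h and 0.50 at 2 h. Among 41 immediate early and short-lived transcripts, 4 rose and 1 fell. The 4 were ID3 (0.55 ± 0.09), NR4A1 (0.36 ± 0.06), ATF3 (0.27 ± 0.05) and ID2 (0.20 ± 0.04), and the list had an adjusted p = 0.299 with an estimated correlation.

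Other genes with the largest changes included NAB2, a corepressor of EGR1, which rose by 0.35 ± 0.05. Those that fell were ARHGAP30 (-0.37 ± 0.06), VDR, the vitamin D receptor (-0.36 ± 0.04), LGALS12 (-0.35 ± 0.05), SLC6A8, the creatine transporter (-0.34 ± 0.07), TCTEX1D1 (-0.33 ± 0.05), PLEK, pleckstrin (-0.30 ± 0.05) and P2RX1, an ATP-gated channel of platelets (-0.29 ± 0.06). Among 45 platelet granule, receptor and structural markers, P2RX1 was the 1 that fell and 1 rose. HMGCS1, an enzyme of cholesterol synthesis, rose by 0.18 ± 0.04 and was the 1 of 23 members of its list to pass (list adjusted p = 0.122 with an estimated correlation). Integrated stress and unfolded protein response mRNAs had a median of -0.04 with none of 34 past the test (adjusted p = 0.122 with an estimated correlation). Oxidative phosphorylation mRNAs, at a median of 0.07, and proteasome mRNAs, at 0.05, had no member past the test and lost their list calls (adjusted p = 0.503 and 0.474 with an estimated correlation). Ribosomal protein mRNAs, translation factors, heat shock mRNAs, megakaryocyte transcription factors, leukocyte markers and nuclear long non-coding RNAs had no list call over all times (camera with limma, BH adjusted p from 0.182 to 0.435). Against 10000 random lists of like expression, only the translation factors among them passed, on the low side (random gene list test, BH adjusted p = 0.026). That test draws genes, which are not independent replicates, and permutes no samples. Among lists of like length and expression, ribosomal proteins, translation factors and megakaryocyte factors stood at percentiles 0.35, 0.9 and 0.95. Heat shock, leukocyte and nuclear lists stood at 49.6, 46 and 96.4.

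In total 81 features were higher and 57 lower in PELO PLPs of 11703 tested (limma-trend, BH), and 1853 had an unadjusted p below 0.05. The balance depended on tool and scaling, with 127 and 159 by DESeq2, 170 and 210 by limma-voom, 165 and 190 by edgeR, and 65 and 66 with median-of-ratios scaling. Leaving out the GFP 2 h or the PELO 2 h library left 16 higher and 11 lower, all among the original calls. A term for depth class left 34 and 26, the same as leaving out GFP 0 h replicate 1. With hour as a factor the term only sets that library apart from its hour, so it does not test depth. The 7 deep libraries, which cover 0 to 2 h alone, gave 1 and 1, with all 138 calls keeping their sign.

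**Figure D2:**
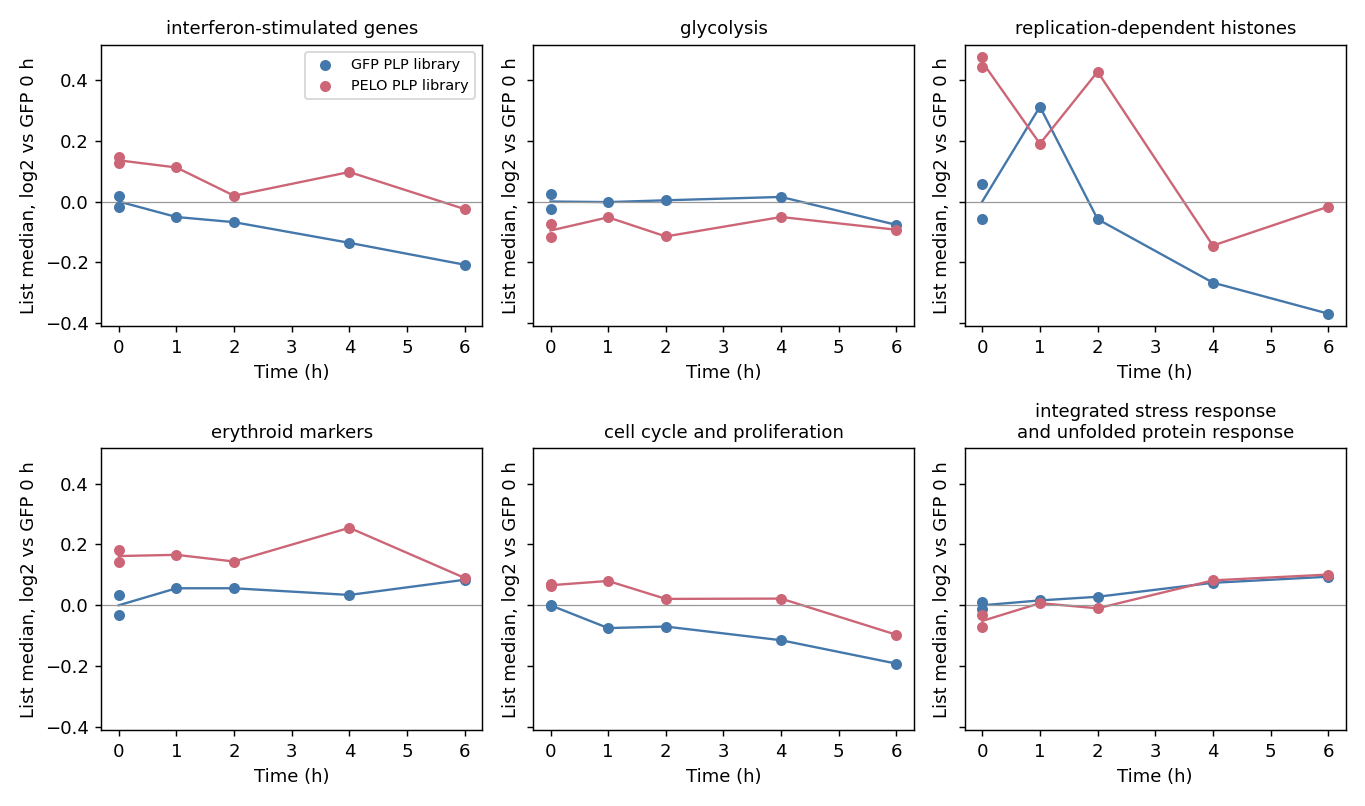
Median log2 level of the members of 6 gene lists in each PLP library, relative to the mean of both GFP 0 h libraries, against time in hours, with 1 point per library and lines through the mean at each time. Interferon-stimulated genes lie higher and glycolysis lower in the PELO than in the GFP library at each of 1, 2, 4 and 6 h. At 6 h the glycolysis points are close, at -0.093 and -0.077. Medians of the differences per gene, which are not the gaps between points, were 0.09 to 0.19 for interferon-stimulated genes. For glycolysis they were -0.09 to -0.06.

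At 0 h, where each condition had 2 replicates, PELO was the 1 feature that passed. It measured 3.48 ± 0.119 RPKM in GFP and 78.9 ± 3.28 RPKM in PELO PLPs (SD, n = 2 each), a log2 change of 4.32 ± 0.06 (limma-trend, BH adjusted p = 8.44e-06). HBS1L measured 8.31 ± 0.642 and 10.4 ± 0.138 RPKM (SD, n = 2 each), a log2 change of 0.31 ± 0.07 that did not pass (limma, BH adjusted p = 0.155). ABCE1 had a log2 change of 0.03 ± 0.06 (limma, BH adjusted p = 0.858). No feature was lower, and 1702 had an unadjusted p below 0.05. With DESeq2, limma-voom and edgeR on the recovered reads, 224, 416 and 241 features were higher and 48, 160 and 62 lower.

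Histone mRNAs had a median log2 difference of 0.45 at 0 h, with all 53 members above 0 and 51 rising when adjusted over the list alone. The members with the smallest p were HIST1H3F (0.58 ± 0.05), HIST1H3H (0.60 ± 0.05), HIST1H2BO (0.55 ± 0.05) and HIST1H2BD (0.45 ± 0.04), none of which passed over all genes. Ribosomal protein mRNAs had a median of 0.19, with 63 of 76 rising when adjusted over the list alone, among them RPL21 (0.27 ± 0.04), RPS20 (0.27 ± 0.04), RPL23A (0.25 ± 0.04) and RPL32 (0.25 ± 0.04). Oxidative phosphorylation mRNAs had a median of 0.22, with 49 of 71 rising when adjusted over the list alone, among them NDUFB11 (0.35 ± 0.05), ATP5E (0.28 ± 0.04), COX5B (0.47 ± 0.07) and NDUFC1 (0.38 ± 0.06). Proteasome mRNAs such as PSMB3 (0.34 ± 0.05) had a median of 0.13. The globin mRNAs HBG1 (0.53 ± 0.05), HBA2 (0.46 ± 0.05), HBA1 (0.40 ± 0.05) and HBE1 (0.40 ± 0.05) had the smallest p of the erythroid list, whose median was 0.18. Interferon-stimulated mRNAs had a median of 0.14, with IFI6 at 0.34 ± 0.05, IFI27 at 0.38 ± 0.06, ISG15 at 0.55 ± 0.08 and OAS1 at 0.31 ± 0.05. Glycolytic mRNAs had a median of -0.10, with HK2 at -0.29 ± 0.05.

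Cell cycle mRNAs, such as PCNA (0.35 ± 0.06), CCNB1 (0.29 ± 0.06) and AURKA (0.31 ± 0.07), had a median of 0.05, and transcripts raised when nonsense-mediated decay is blocked, such as DDIT3 (0.38 ± 0.07), ATF3 (0.42 ± 0.08) and SNHG8 (0.41 ± 0.11), had a median of 0.09. All 9 of these lists passed with the preset correlation, and each lost its call with an estimated one (camera with limma, BH adjusted p from 0.242 to 0.437). Feature length moved with the condition at this time. Features under 1000 nt stood lower relative to features over 4000 nt in both GFP 0 h libraries, by -0.21 and -0.29 on the log2 scale, while the 10 other libraries lay between -0.04 and 0.18. Across 9077 features the 0 h change fell with length (Spearman rho -0.49; genes are not independent replicates), and ribosomal protein mRNAs had a median length of 737 nt. With the length trend of each library removed, the 0 h medians went from 0.19 to 0.07 for ribosomal proteins, 0.22 to 0.11 for oxidative phosphorylation, 0.13 to 0.08 for the proteasome, 0.18 to 0.12 for erythroid markers, 0.45 to 0.34 for histones and 0.05 to 0.10 for the cell cycle. The removal was partial, since the Spearman rho with length was still -0.112 afterwards.

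The next question was how the RNA of PLPs changed over 6 h. The median of all features moved by -0.11 in GFP and by -0.10 in PELO PLPs over 6 h on the log2 scale, so each change below should be set against that shift, whose source was not tested. Integrated stress and unfolded protein response mRNAs rose as a group in both conditions. Of 34 measured, 9 rose and 2 fell in GFP (10 and 2 adjusted over the list alone), and 8 rose and none fell in PELO PLPs (11 and 1). HSPA5, the main chaperone of the endoplasmic reticulum, rose over 6 h by 0.61 ± 0.07 in GFP and 0.42 ± 0.07 in PELO PLPs. In GFP, PHGDH and PSAT1, enzymes of serine synthesis, rose by 0.45 ± 0.08 and 0.37 ± 0.09 and AARS, an alanyl-tRNA synthetase, by 0.35 ± 0.08. The AARS slope was -0.0057 per hour in the 7 deep libraries alone, whose GFP members are 0 h replicate 2, 1 h and 2 h. In PELO PLPs, SESN2 rose by 0.38 ± 0.09, SLC7A5, an amino acid transporter, by 0.35 ± 0.08 and PDIA4 by 0.25 ± 0.06. The list passed with an estimated correlation in both (camera with limma, BH adjusted p = 0.00901 in GFP and 0.00603 in PELO).

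Histone mRNAs fell in both conditions, with a median change of -0.46 over 6 h in GFP and -0.54 in PELO PLPs. Of 53 members, 20 fell in GFP (32 adjusted over the list alone) and 26 in PELO PLPs (44), and none rose. In GFP, HIST1H4A changed by -0.75 ± 0.19, HIST1H2BJ by -0.74 ± 0.21 and HIST1H2BO by -0.73 ± 0.15. In PELO PLPs, HIST1H3F changed by -0.88 ± 0.18, HIST1H3A by -0.88 ± 0.23, HIST1H2AB by -0.79 ± 0.16 and HIST1H2AJ by -0.74 ± 0.16. The list calls were lost with an estimated correlation (adjusted p = 0.732 in GFP and 0.752 in PELO).

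Cell cycle mRNAs had 3 members rising and 14 falling in GFP and 3 and 11 in PELO PLPs, of 39 measured. CCNA2 changed by -0.46 ± 0.08 and -0.50 ± 0.08, CDC6 by -0.36 ± 0.06 and -0.32 ± 0.06, and PLK1, a mitotic kinase, by 0.52 ± 0.08 and 0.39 ± 0.08. Interferon-stimulated mRNAs had 3 rising and 13 falling of 30 in GFP and 2 and 9 in PELO PLPs, with DDX58, an RNA sensor, at -0.46 ± 0.08 and -0.50 ± 0.08 and IFI44L at -0.41 ± 0.07 and -0.35 ± 0.07. Neither list passed against the shift of all features (camera with limma, BH adjusted p from 0.211 to 0.344). EGR1, an immediate early transcription factor, rose by 0.59 ± 0.10 in both conditions, and BTG2 fell, with changes of -0.69 ± 0.08 and -0.41 ± 0.08. Of 45 platelet markers, 6 rose and 5 fell in GFP and 4 and 5 in PELO PLPs, and the list passed as higher than all features with the preset correlation (camera with limma, BH adjusted p = 0.0211 and 0.00367) but not with an estimated one (0.589 and 0.512). FCER1G rose by 0.52 ± 0.07 and 0.35 ± 0.07, while RGS18 changed by -0.54 ± 0.09 and -0.45 ± 0.09 and TUBB1, the platelet tubulin, by -0.37 ± 0.07 and -0.49 ± 0.07.

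Most factors of ribosome rescue and mRNA decay did not pass. In GFP PLPs 5 of 20 rescue factors, 7 of 17 of the exosome and SKI complex, 9 of 32 of decapping and deadenylation and 5 of 17 of nonsense-mediated decay fell, and in PELO PLPs 3, 3, 5 and 4. LTN1, the ubiquitin ligase of stalled ribosomes, changed by -0.51 ± 0.10 in GFP and -0.42 ± 0.10 in PELO PLPs, and DIS3L by -0.41 ± 0.08 and -0.29 ± 0.08. SMG8 changed by -0.47 ± 0.07 in each. CNOT3, a deadenylase subunit, rose by 0.67 ± 0.11 in GFP PLPs, with a slope of the other sign in the 7 deep libraries alone (-0.011 per hour). None of the 4 lists of such factors passed against the shift of all features. Ribosomal protein mRNAs had a median change of 0.15 in GFP and 0.04 in PELO PLPs, with 3 and 2 of 76 rising and lost list calls (adjusted p = 0.603 and 0.752 with an estimated correlation). With the length trend of each library removed the GFP median went from 0.0256 to 0.0059 per hour and the PELO median from 0.0071 to 0.00015, with list calls of 3.78e-10 and 0.0037 (camera with limma, BH adjusted p, preset correlation). Across features the slopes still had a Spearman rho with length of -0.0801 in GFP and -0.0108 in PELO PLPs. Without the removal, both slopes of the list stood at percentile 100 of lists of like length and expression. RPS16 rose by 1.74 ± 0.38 and 1.23 ± 0.38, and EIF1, an initiation factor, by 0.98 ± 0.15 and 0.79 ± 0.15. The 6 listed copies of mitochondrial ribosomal RNA (MTRNR2L genes) had larger rises than either, with a median fold of 5.53 between 0 and 6 h in GFP and of 2.98 between both GFP libraries at 0 h. Across the libraries 69 features followed these copies at r above 0.9, 65 of them among the 339 that rose in GFP. RPS16 (r = 0.971) and EIF1 (r = 0.981) were among the 69. RPS16 was 2.31-fold higher in GFP 0 h replicate 2 than in replicate 1. Its GFP slope changed sign in the 7 deep libraries alone (-0.076 per hour), where replicate 2 is the only GFP library of 0 h.

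PELO mRNA itself changed by -0.27 ± 0.08 over 6 h in GFP (limma, BH adjusted p = 0.0328) and by 0.18 ± 0.08 in PELO PLPs (0.158). ABCE1 fell in PELO PLPs, with a change of -0.28 ± 0.07 (limma, BH adjusted p = 0.0298), while HBS1L changed by -0.09 ± 0.07 (0.387). The HBS1L value is near the median of all features, -0.10. Its sign turned positive with median-of-ratios scaling, which takes that shift out, so the reversal says nothing about HBS1L itself.

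In GFP PLPs 339 features rose and 2039 fell, and in PELO PLPs 230 rose and 1410 fell (limma-trend, BH). Both conditions shared 143 rising and 863 falling features, where 6.66 and 246 would be shared if the calls were independent. The calls were not independent, since both slopes came from 1 fit with a shared variance per gene and a like shift of all features. The excess over 6.66 and 246 therefore does not measure agreement between the conditions. Across genes, which are not independent replicates, the slopes had a Pearson r of 0.531. With median-of-ratios scaling, which takes the shift of all features out, 746 rose and 590 fell in GFP and 429 and 320 in PELO PLPs. A depth-class term gave 395 and 2277 in GFP and 90 and 805 in PELO PLPs, whose libraries of 0 to 2 h were all deep and those of 4 and 6 h all shallow. Without the 6 h library of the condition, 12 rose and 64 fell in GFP and none passed in PELO PLPs.

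**Figure D3:**
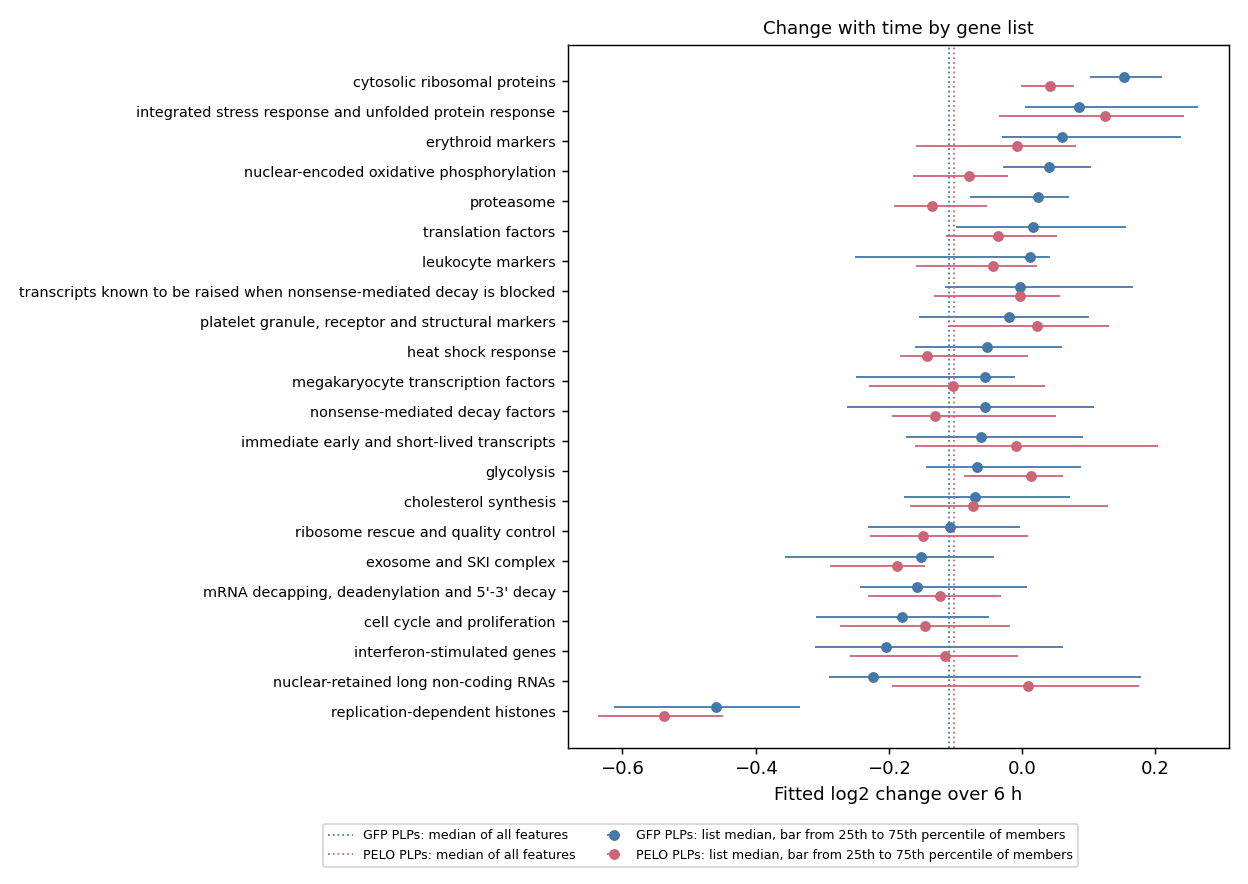
Fitted log2 change over 6 h of each gene list in GFP and PELO PLPs. Points are list medians, bars run from the 25th to the 75th percentile of members, and dotted lines mark the median of all features, -0.11 in GFP and -0.10 in PELO PLPs. Histones have the lowest medians, -0.46 and -0.54.

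The slopes of PELO and GFP PLPs were then compared directly. No feature passed in either direction (limma-trend, BH), with 728 at an unadjusted p below 0.05, and edgeR, DESeq2 and limma-voom on the recovered reads also gave 0. The smallest p belonged to LZIC (difference over 6 h 0.60 ± 0.13), CCDC61 (0.69 ± 0.15) and ZNF551 (0.54 ± 0.12) on the higher side. On the lower side, ORMDL1 (-0.45 ± 0.10) and TRAPPC2 (-0.49 ± 0.11) were among those with the smallest p. The slope of PELO mRNA differed by 0.45 ± 0.11 (limma, BH adjusted p = 0.513), that of HBS1L by 0.00 ± 0.10 and that of ABCE1 by -0.06 ± 0.11. Ribosomal protein mRNAs such as RPL8 (-0.20 ± 0.13), oxidative phosphorylation mRNAs such as SDHB (-0.29 ± 0.11) and proteasome mRNAs such as PSMA3 (-0.35 ± 0.12) had list medians of -0.13 each over 6 h. Translation factors such as EIF3F (-0.21 ± 0.10) had a median of -0.07. These 4 lists passed with the preset correlation, and all lost their calls with an estimated one (adjusted p = 0.973 for each). In simulated data of this design, 71% of features with a 2-fold difference over 6 h and 20% with a 1.5-fold difference were recovered. These shares may overstate recovery here, since many features were changed at once and each was drawn independently, without a length trend.

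The last question was how PLPs compare with primary platelets. In the 2 platelet libraries, mRNAs of typical platelet proteins were among the highest symbols. B2M had 453115 ± 60673 reads (SD, n = 2), TMSB4X, thymosin beta 4, 408245 ± 42861, and PPBP, the precursor of the platelet chemokine NAP-2, 376421 ± 50507. RGS18 had 215424 ± 30927 and SDPR 207005 ± 30579 reads. FAM190A, KIAA1680 and TMSL3, with 215828, 215804 and 215678 reads, had nearly equal counts, and TMSL3 is a thymosin beta 4 pseudogene. PARG and TIMM23, at 156767 ± 19921 and 155918 ± 19795 reads, were also nearly equal to each other and to NCOA4 (154827 ± 19639, named after its values were seen). Whether such counts are shared reads was not tested. PF4 had 19053 ± 1140 and ITGA2B 5976 ± 797 reads. The 5 highest symbols were SDCCAG1, PTPRD, ANKRD28, KIAA0379 and PLXND1, with means from 951329 to 1802621 reads. PTPRD, ANKRD28 and PLXND1 span a copy of 7SL RNA, the abundant RNA of the signal recognition particle, in GENCODE, as 1.98% of genes in both tables do. SDCCAG1 (now NEMF) lies within 5000 nt of the 7SL gene RN7SL3, and KIAA0379 could not be matched by name. KIAA0379 and ANKRD28 had nearly equal counts, 1104309 and 1117468 reads, so these 5 symbols need not be 5 separate loci. Whether reads of these 5 symbols come from 7SL RNA was not tested, so their counts are not interpreted here as mRNA levels.

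Platelet granule, receptor and structural markers had a median rank percentile of 98.7 in platelets and 56.1 in GFP PLPs at 0 h, over the 44 members in both tables, 42 of which ranked higher in platelets. Another 25 had no PLP row, among them PF4 and PPBP, and 33 of the 100 highest platelet symbols had none. Symbols were matched by name alone, so a gene listed under another name counts as missing. SDCCAG1 is among the 33, although NEMF, its current name, was measured in the PLPs. ITGA2B stood at percentile 97.8 in platelets and 93.5 in PLPs, and GATA1, a megakaryocyte transcription factor, at 68.5 and 87.4. MALAT1, a nuclear long non-coding RNA, had 13.6 ± 2.81 RPKM in PLPs (SD, n = 2) and no platelet row. Ribosomal protein mRNAs stood at a median percentile of 75.3 in platelets and 99.3 in PLPs, with none of 76 higher in platelets. Proteasome mRNAs stood at 54.7 and 87.3, and heat shock mRNAs at 61.9 and 94.8. Erythroid markers stood at 64.0 and 45.3 over 23 members, with HBB at 97.9 and 6.5 and HBG1 at 71.6 and 99.7, both named after their values were seen. Leukocyte markers, which other blood cells in a platelet preparation would bring, stood at medians of 30.8 in platelets and 29.6 in PLPs over the 9 members in both tables, 6 of which ranked higher in platelets, with a median difference per gene of 19.4. Another 25 leukocyte markers had no PLP row. PELO ranked at 43.3 and 50.4, HBS1L at 66.1 and 91.9 and ABCE1 at 67.3 and 96.2.

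Over all 29158 symbols of the platelet table, 21469 of them with a count, the rank correlation between both platelet libraries was 0.943. Across the 10206 symbols in both tables it was 0.425 between platelets and GFP PLPs at 0 h, with 0.411 to 0.434 over the 4 pairings of libraries. Genes are not independent replicates, and no test was made across the tables. With RPKM in place of CPM for the PLPs, the correlation was 0.278.

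**Figure D4:**
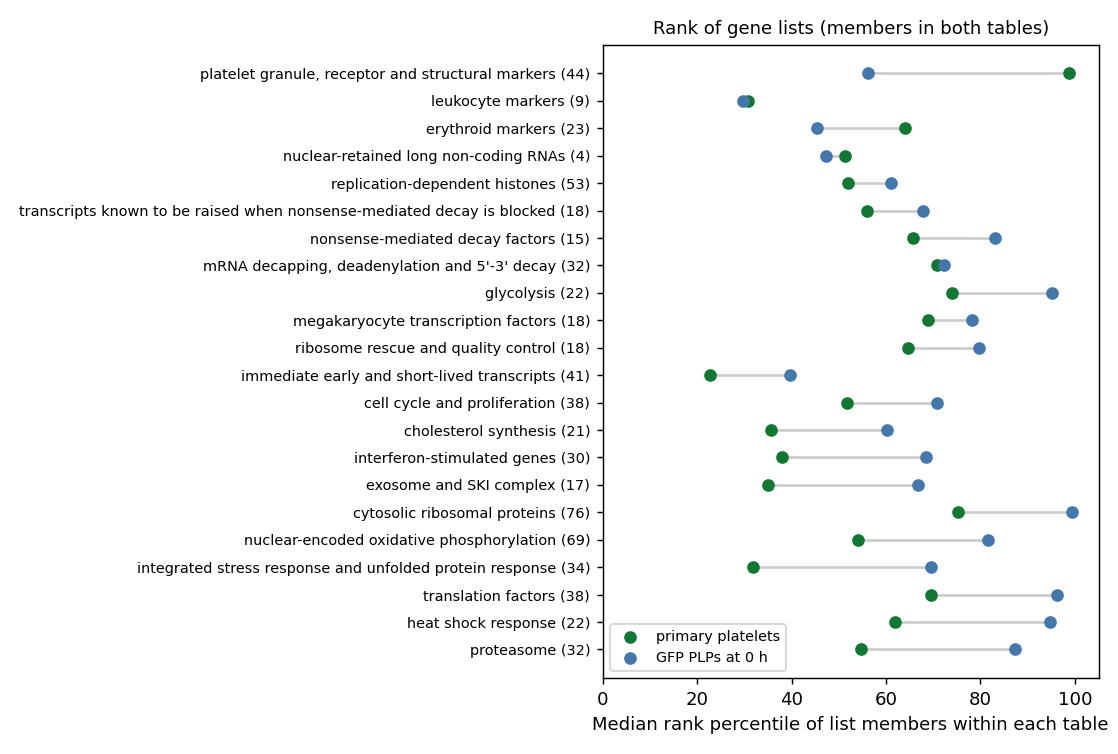
Median rank percentile of each gene list within primary platelets and within GFP PLPs at 0 h, over the members in both tables (number in brackets). Platelet markers stand at 98.7 in platelets and 56.1 in PLPs, and ribosomal proteins at 75.3 and 99.3.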

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

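The comparison of list slopes was planned, and the tests of feature length, depth and times below were chosen after the result was seen.

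In 4 lists the change over time differed between PELO and GFP PLPs when tested directly with the preset correlation. Slopes were lower in PELO PLPs for cytosolic ribosomal proteins (camera with limma, BH adjusted p = 5.37e-05, 75 of 76 members below 0), oxidative phosphorylation (2.3e-05, 65 of 71), the proteasome (5.59e-05, 28 of 32) and translation factors (0.0467, 28 of 38). The adjusted p was 0.973 for each with an estimated correlation, and no member passed alone. With the length trend of each library removed the adjusted p was 0.00131, 0.00172, 0.00386 and 0.0968, and the medians per hour went from -0.0217 to -0.0109, -0.0224 to -0.0124, -0.0218 to -0.0129 and -0.0109 to -0.0070. The removal was partial, since the Spearman rho between length and slope difference went from 0.319 to 0.0809. Among lists of like length and expression the slope differences stood at percentiles 55.0, 37.5, 4.2 and 6.55. In this difference ribosomal protein and oxidative phosphorylation mRNAs thus moved like other features of their length and expression. At 0 h, however, oxidative phosphorylation and proteasome means stood at percentiles 99.9 and 98.1 of such lists, above most features of like length. Translation factors stood at 12.8 at 0 h.

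The ribosomal protein list was also higher in PELO PLPs at 0 h, and the low level of short features in the GFP 0 h libraries is a candidate cause of both. Its mean at 0 h stood at percentile 66.7 of lists of like length and expression, so its members moved like other short features. Depth is argued against, since GFP 0 h libraries of 15.9 and 105.1 M reads both stood low, the higher at -0.21 in short minus long features. An effect of PELO at every time is argued against too, since PELO stood above GFP in this measure at 2 of 4 times after 0 h. Removing the length trend left a 0 h median of 0.07 of 0.19. The removal was partial, since the Spearman rho between length and 0 h change went from -0.49 to -0.112. What was left may still hold an effect of length. Length as the whole cause therefore stays open, as does a difference between PELO and GFP at 0 h alone.

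Histone mRNAs are shorter still, at a median of 460 nt, but their mean at 0 h stood at percentile 100 of lists of like length and expression. That value argues against a length trend shared by all features of their length bin as the whole cause. The lists were matched in 10 length bins, so a trend within the shortest bin was not matched and stays open. A difference due to PELO also stays open and was not tested apart from other differences between the GFP and PELO samples.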

How the results depend on the processing

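Planned were median-of-ratios scaling, the filter of 5 CPM, DESeq2, limma-voom, time as a rank, fits without 6 h, hour as a factor, the replicate block, the 0 h contrast from 12 libraries, estimated correlation, random lists and leaving out libraries, while edgeR on the recovered reads, pseudocounts, the filter of 1 RPKM, the length, depth and deep-library tests, transcript sums and RPKM ranks were chosen after seeing the data. Of 7057 values of named genes, 5480 kept direction and side of the threshold, 1285 fell short of it, 266 newly passed and 26 reversed. Of 152 list values, 102 stayed, 49 fell short and 1 reversed. Where no cause is given, the cause was not tested.

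For PELO against GFP at 0 h (1 higher and 0 lower), the counts were 44 and 3 with median-of-ratios scaling, 83 and 4 with at least 5 CPM, 25 and 1 with at least 1 RPKM, 224 and 48 with DESeq2, 416 and 160 with limma-voom, 241 and 62 with edgeR, and 11 and 10 from all 12 libraries. They stayed 1 and 0 with other pseudocounts and with length removed, and PELO passed under each of these. Leaving out 1 library gave 1 to 129 higher and 0 to 35 lower, with the lone sample assumed to vary like the others: 81 and 5 without GFP replicate 1, 129 and 35 without GFP replicate 2, and 2 and 0 without PELO replicate 2. ABCE1 ran from -0.037 without GFP replicate 1 to 0.099 without GFP replicate 2.

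For the change in GFP PLPs (339 and 2039), the counts were 746 and 590 with median-of-ratios scaling, 598 and 428 with DESeq2, 375 and 247 with limma-voom, 489 and 406 with edgeR, 29 and 158 without 6 h, and 0 and 0 in the 7 deep libraries alone, which end at 2 h. Median-of-ratios scaling moves the median of all features to near 0, and 339 and 590 of the calls were kept. Leaving out 1 library gave 12 to 392 higher and 64 to 2321 lower, with 12 and 64 without GFP 6 h and 193 and 1083 without GFP 0 h replicate 1. In the deep libraries alone the log2 change per hour reversed for MTRNR2L10 (-0.16), MTRNR2L6 (-0.14), MTRNR2L3 (-0.036), MTRNR2L8 (-0.13), MTRNR2L2 (-0.20), MTRNR2L1 (-0.18), RPS16 (-0.076), HNRNPH3 (-0.22), CNOT3 (-0.011), UPF3A (0.022), PABPC1 (-0.028), EIF3C (-0.036), HIST1H1B (0.041), FOSB (-0.0081), AARS (-0.0057), PGAM1 (0.020) and PSMD14 (0.035). These slopes rest on 1 GFP library each at 0 h (replicate 2), 1 h and 2 h.

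For the change in PELO PLPs (230 and 1410), the counts were 429 and 320 with median-of-ratios scaling, 514 and 312 with DESeq2, 352 and 186 with limma-voom, 416 and 310 with edgeR, 90 and 805 with a depth-class term, 0 and 0 without 6 h, and 1 and 0 in the 7 deep libraries alone. Leaving out 1 library gave 0 to 278 higher and 0 to 1724 lower: 0 and 0 without PELO 6 h, 113 and 493 without PELO 0 h replicate 1, 69 and 431 without replicate 2, and 147 and 806 without PELO 1 h. HBS1L per hour was 0.0047 with median-of-ratios scaling, 0.0043 with DESeq2, 0.0029 with limma-voom and 0.0033 with edgeR. Each of these settings brings the median of all features near 0, so the sign of this small value depends on the scaling. In the deep libraries MAGOHB was 0.0025 and AHSP 0.14. With length removed, 295 features rose and 2051 fell.

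For the slope difference, each tool and each library left out gave 0 and 0, except 2 and 0 in the 7 deep libraries and 0 and 1 with length removed. In the deep libraries LZIC was -0.033 and NDUFB3 0.013. Translation factors reversed against 10000 random lists of like expression (random gene list test, BH adjusted p = 0.99), standing at percentile 55.7 of them.

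For PELO against GFP over all times (81 and 57), the counts were 162 and 93 with at least 5 CPM, 127 and 159 with DESeq2, 170 and 210 with limma-voom, 165 and 190 with edgeR, 155 and 90 with length removed, 34 and 26 with a depth-class term, and 1 and 1 in the 7 deep libraries. The depth-class term amounts here to leaving out GFP 0 h replicate 1, the only library it sets apart from its hour. Leaving out 1 library gave 16 to 122 higher and 11 to 54 lower: GFP 0 h replicate 1 34 and 26, replicate 2 41 and 31, GFP 1 h 122 and 54, 2 h 16 and 11, 4 h 27 and 16, 6 h 27 and 15, PELO 0 h replicate 1 16 and 12, replicate 2 18 and 14, PELO 1 h 122 and 53, 2 h 16 and 11, 4 h 28 and 16, 6 h 27 and 15. Median-of-ratios scaling gave 65 and 66.

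With the replicate number as a block, the counts were 145 and 40 at 0 h, 44 and 35 over all times and 0 and 0 for the slope difference. The numbers do not pair the 0 h libraries (correlation 0.0535).

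The rank correlation of platelets and PLPs (0.425) was 0.278 with RPKM, 0.309 with at least 5 CPM in the PLPs, 0.427 with transcripts summed, and 0.413 to 0.437 when 1 library was left out.

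Library totals alone and no low filter are the values as reported. Not run were scaling to luciferase and the removal of mitochondrially encoded genes (no such features), tests, scaling and blocks across platelets and PLPs (tables with different units), and a pseudocount for platelets (counts). Depth limits the 5 shallow libraries, where 3 reads per kb are 0.225 RPKM in PELO 4 h, 0.188 in GFP 0 h replicate 1, 0.183 in GFP 6 h, 0.142 in GFP 4 h and 0.138 in PELO 6 h, a limit from counting error alone.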

Other observations

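All tests in this part were chosen after the result was seen.

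Interferon-stimulated mRNAs were higher and glycolytic mRNAs lower in PELO PLPs over all times. With the length trend removed, at least 91.7% of each list's median change was left, which argues against feature length. Leaving out any 1 of the 12 libraries left at least 79.6% of it, with medians of 0.15 to 0.18 for interferon-stimulated mRNAs and -0.07 to -0.10 for glycolysis, which argues against a single library. A difference due to PELO and one between the GFP and PELO samples that is not due to PELO both stay open, and no test here separates them.

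Copies of mitochondrial ribosomal RNA rose with time in both conditions, yet they differed by a median fold of 2.98 between the 2 GFP libraries at 0 h, where 99% of all features lay below 1.33. Residual ribosomal RNA that differs between libraries could give such values. The median fold of 6 h over 0 h in GFP was 5.53, and with 1 library at 6 h a change with time cannot be told apart from it.

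Other groupings of the libraries were fitted in the same way. For PELO against GFP over all times, 1 of 100 splits, the real one, gave as many genes (138, highest other 91, in a split that keeps 5 of the 6 GFP libraries together). A random split of these libraries thus seldom gives this count, and 1 in 100 is the lowest share that 100 splits can show. A chance difference between cultures cannot be excluded, since the labels do not say which libraries share one. For the difference between slopes the real count was 0, which any split matches (100 of 100, highest other 24), so this count says nothing about chance. For the orders of the times, 1 of 100, the real one, gave as many genes in GFP PLPs (2378, highest other 1760) and 1 of 100 in PELO PLPs (1640, highest other 1501). These highest orders nearly keep the time axis: the GFP one reverses it except for 1 and 2 h, and the PELO one swaps 2 and 4 h. The median of the other orders was 0 in both conditions.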
